A study of Saccharomyces cerevisiae BY4743 with 24 samples.

How the data were processed

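The series holds 24 libraries of Saccharomyces cerevisiae BY4743, a diploid strain. Per the labels' protocols, cells grew at 30 °C in synthetic medium with raffinose to mid-log phase and were sampled there, or were filtered, resuspended in medium at 42 °C and sampled after 30 min. Cycloheximide was added at harvest, lysates ran on sucrose gradients, fractions were joined into pools by the absorbance profile, each pool received spike-in RNA, and libraries were made with Stranded SMART-Seq without depletion of rRNA. The 2 temperatures, 4 pools and 3 replicate numbers make 8 groups from 6 gradients, with each library's group read from its title. Nothing in the labels says that replicates are separate cultures, so a p-value here measures the spread between these samples.

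Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.5 and quantified with Salmon 1.9.0 against build R64; their settings are not given in the sources used here. The deposited table holds TPM (transcripts per 1000000) for 6087 entries: 5959 mRNAs, 5 rRNAs, 113 other non-coding RNAs, 5 further RNAs and 5 spike-ins. Its columns sum to between 999968 and 999999, and 3 emptied lines were skipped. All 6082 gene IDs matched the reference table, which gave the symbols, including those of 2 genes whose symbols the deposited table had turned into dates; 0 value columns were left without a sample. TPM keeps no read depth, so depth per library is unknown. The precision was read instead from the replicates and from values at 0: the correlation between replicates of a group ran from 0.75 (42 °C, pool 1) to 0.95 (30 °C), and 673 to 882 mRNAs were listed at 0 per library at 30 °C and 843 to 1415 at 42 °C. An entry at 0 in all libraries of a group is called listed at 0 and given no fold. Reads of near-identical paralogs are split between them by the quantification.

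Gene levels were TPM rescaled to a sum of 1000000 over the mRNA entries (mRNA TPM), because rRNA takes most of each library and its share differs between pools. Genes with at least 10 mRNA TPM in at least 3 libraries were kept, 3949 in all, and log2 of mRNA TPM plus a pseudocount of 1 was fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean-variance trend, 1 mean per group and Benjamini-Hochberg adjustment at 5%, 2-sided. The comparisons were heat in each pool, heat over the mean of the 4 pools of each gradient, pool 4 against pool 1 at each temperature, and the heat change of that pool difference. The mRNA to rRNA ratio of each library was the sum of mRNA TPM over the sum of rRNA TPM, compared as log2 by exact permutation of 3 against 3 samples in 6 comparisons. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.

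Of 20 gene lists, 18 with at least 5 tested genes were tested with limma camera at an inter-gene correlation of 0.01 and again with an estimated correlation and with limma fry, whose PValue asks for movement one way. The list of other non-coding RNAs was tested in a separate fit of these RNAs together with the mRNAs, and the list of mitochondrially encoded mRNAs was not used because the table has 0 such entries. The lists, the comparisons, the scaling and the rule for naming genes were set before the data were examined. Under that rule the genes named are those with the largest changes past 5% with a mean of at least 20 mRNA TPM and non-overlapping samples, abundant members of each list and a fixed set (such as HSP104, ACT1 and STM1). Genes that went against their list were named after their values were seen.

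Alternatives were pseudocounts of 0.1 and 5, no filter and a filter of 50 mRNA TPM, TPM as deposited, median, quantile and spike-in scaling, no trend, a change of at least 1 on the log2 scale, blocks, single pools, other contrasts of the pools, leaving out each gradient, and other sums for the ratio. The 25S rRNA scale, the spike-in scale with a block, mRNA over spike-in within replicates 2 and 3, genes of at least 600 nt, the fits without the 42 °C pool 1 libraries, pool 3 in place of pool 4 at 30 °C median scaling of the lists (with an estimated correlation too) and TPM as deposited with a pseudocount of 0.0224, scaled to the mean mRNA sum, were added after the data were seen.

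Whether replicate numbers pair the samples was checked by correlating residuals: at the same number, r was 0.03 to 0.10 between temperatures within a pool, and 0.15, 0.14 and 0.19 between gradient means. At different numbers within a pool the mean was −0.03 and the highest value 0.02. Each same-number value within a pool lay above that highest value, so a weak link between samples of one number is not excluded. Within pools the samples were treated as unpaired, and gradient means were also fitted with the number as a block. Pools of one gradient share it by design, with r of 0.05 to 0.34.

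The fits were tested on simulated data in which 200 of 3949 genes changed. The percent recovered at 2-, 4- and 8-fold was 11.7, 50.0 and 86.6 for heat in pool 1, 14.5, 56.7 and 77.5 in pool 2, 6.0, 61.9 and 85.7 in pool 3, and 11.8, 58.1 and 86.2 in pool 4. It was 25.4, 73.4 and 90.3 for heat over the pools, 12.1, 62.8 and 87.5 for pool 4 against pool 1 at 30 °C, 11.6, 69.0 and 76.7 at 42 °C, and 0, 33.8 and 52.4 for the heat change of that difference. False calls were 5, 1, 7, 4, 10, 2, 1 and 0 in the same order, with 0 wrong signs. Of 18 simulated lists of 30 genes, 6 shifted by 1 on the log2 scale were recovered, all 6, with the preset and with the estimated correlation, with 0 false. Simulated genes varied independently of each other, so this cannot tell which correlation suits the real lists. Noise was normal, with 1 spread per gene for all groups and no excess of values at 0. In the real groups the median SD of a gene ran from 0.32 (30 °C, pool 2) to 0.64 (42 °C, pool 1).

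Left out were single transcripts of the 5 further RNAs, read-level analysis and positions along the gradient within a pool, which are not analysed here. Lengths are those of the reference table and include introns; 96.4% of them are multiples of 3. Spike-in levels differed between replicate numbers (mean TPM 45.3, 420.3 and 380.7 for numbers 1 to 3), so the spike-in scale served as an alternative.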

Results

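Polysome gradients of the diploid yeast BY4743 at 30 °C and after 30 min at 42 °C were compared in 24 RNA libraries: 4 gradient pools, 2 temperatures and 3 replicates of each. Library names call the first 3 pools mono, di and tri. The series title puts the question of silent ribosomes and mRNA turnover in heat shock, which was addressed through the mRNA to rRNA ratio of each pool and through the level of each mRNA. Cells at 42 °C were also filtered and resuspended and cells at 30 °C were not, so every comparison of temperature includes that handling. Gene levels are mRNA TPM (TPM rescaled so that the nuclear protein-coding mRNAs of a library sum to 1000000), and n is 3 gradients per temperature throughout.

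Less mRNA went with ribosomal RNA in pool 1 after heat. In pool 1, 1000 TPM of rRNA went with 24.1 ± 1.52 TPM of mRNA at 30 °C and with 2.65 ± 1.31 at 42 °C (mean ± SD, n = 3), 9.90-fold less as geometric means. Against the 25S rRNA of the large subunit alone, the mRNA per 1000 TPM in pool 1 was 69.9 ± 5.84 at 30 °C and 15.2 ± 0.74 at 42 °C. Pool 2 went from 110.1 ± 10.2 to 39.1 ± 7.96, pool 3 from 90.9 ± 5.55 to 66.5 ± 7.32, and pool 4 from 55.5 ± 5.77 to 54.3 ± 1.09. Over all rRNA the log2 differences were −3.31, −1.15, −0.52 and 0.12 in pools 1 to 4, −1.21 as the mean of the pools and 3.43 for pool 4 minus pool 1. In pools 1 to 3 each of the 3 libraries at 42 °C lay below each at 30 °C, and in pool 4 each lay above. With 25S rRNA alone the pool 1 and pool 2 differences were −2.20 and −1.51, and that of pool 4 was −0.03, the opposite sign. Without the 20 most abundant mRNAs pool 4 was at −0.39, also of the opposite sign, so no direction is given for pool 4. Two-sided exact permutation gave p = 0.1 for each of the 6 differences over all rRNA, the smallest that 3 against 3 samples can give, and the Benjamini-Hochberg values over these 6 were also 0.1, so none passed 5%. With samples paired by replicate number, exact sign flips gave p = 0.25 for each, the smallest that 3 pairs can give.

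**Figure D1:**
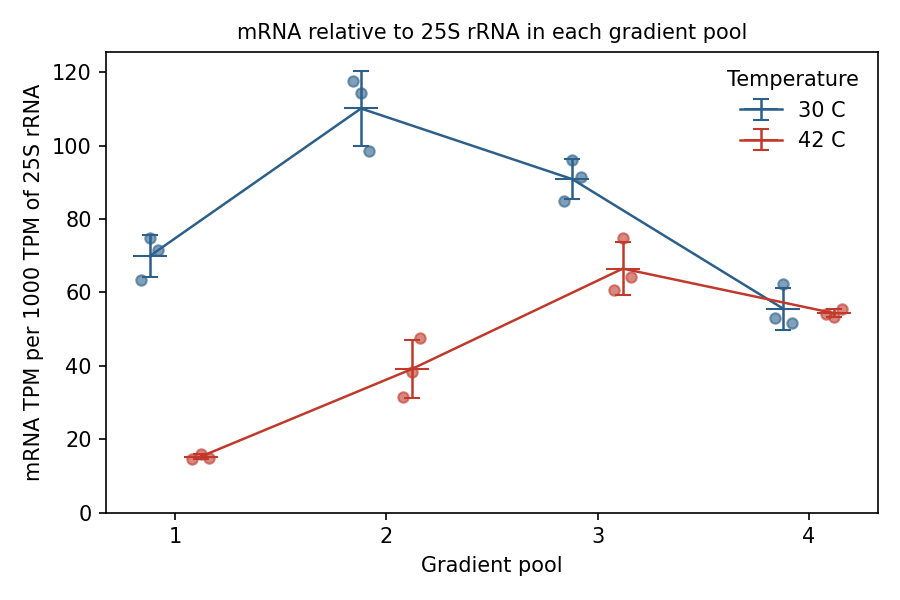
TPM of mRNA per 1000 TPM of 25S rRNA in each gradient pool at 30 °C and 42 °C. Points are libraries, bars are mean ± SD of n = 3.

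Cytoplasmic ribosomal protein mRNAs held a larger share of the mRNA at 30 °C than at 42 °C in each pool. Their share of mRNA TPM at 30 °C was 65.1 ± 0.79% in pool 1, 63.0 ± 1.65% in pool 2, 58.5 ± 3.72% in pool 3 and 45.7 ± 5.12% in pool 4 (mean ± SD, n = 3). At 42 °C the shares were 3.86 ± 1.44%, 3.25 ± 1.30%, 1.71 ± 0.67% and 0.90 ± 0.41%. The other mRNAs, set against 25S rRNA, were lower at 42 °C in pool 1 by a log2 difference of −0.73 and higher in pools 3 and 4 by 0.79 and 0.84 (pooled SD 0.13, 0.19 and 0.18). In pool 2 they were at −0.12 (pooled SD 0.23) and over the 4 pools at 0.20 (pooled SD 0.14). All mRNAs over 25S rRNA were at −1.51 and −1.05 there.

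**Figure D2:**
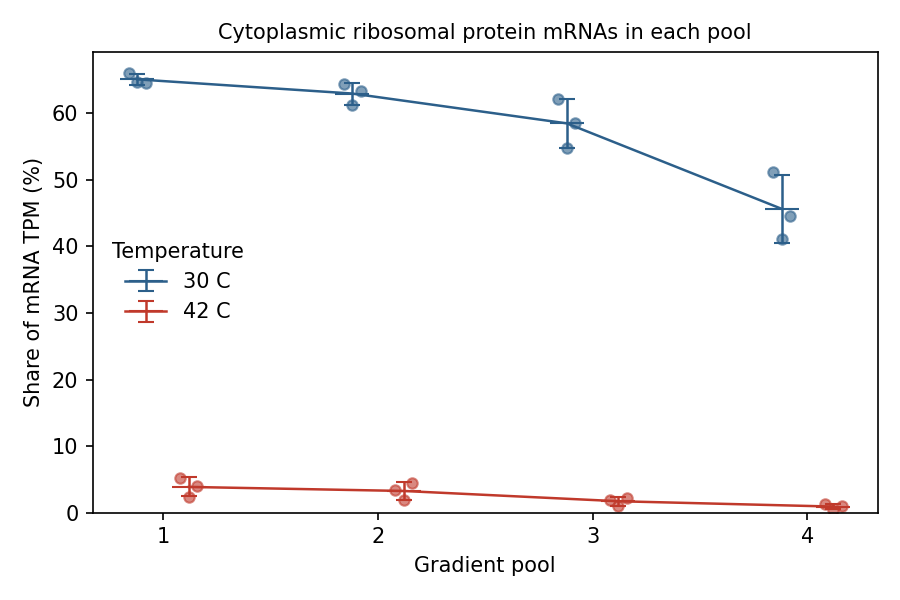
Percent of mRNA TPM held by cytoplasmic ribosomal protein mRNAs in each pool at 30 °C and 42 °C. Points are libraries, bars are mean ± SD of n = 3.

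Chaperone and stress mRNAs rose with heat over the 4 pools. The disaggregase mRNA HSP104 went from 48.0 ± 3.93 to 6814 ± 1436 mRNA TPM (mean ± SD of gradient means, n = 3), the Hsp90 mRNA HSP82 from 83.6 ± 2.08 to 6420 ± 1243, and the Hsp70 mRNA SSA4 from 4.29 ± 1.04 to 7168 ± 1691; HSP82 and the SSA mRNAs have close paralogs, between which reads are split. Their single values are uncertain. HSP12 went from 4570 ± 3419 to 76710 ± 3424, and KAR2, the Hsp70 of the endoplasmic reticulum, from 17.9 ± 0.87 to 555.3 ± 30.4. Among cytosolic chaperones that are Hsf1 targets 22 of 22 genes rose, and among general stress genes 24 of 24, including HOR7 (log2 4.23) and TMA10 (1.96). Mitochondrial chaperones rose in 5 of 6 tested, with HSP78 at 6.32, HSP60 at 2.34 and SSC1 at 1.24, and MGE1 fell by 1.54. Chaperones of the endoplasmic reticulum rose in 8 of 9, with ERO1 at 4.21 and PDI1 at 2.13, and CNE1 fell by 1.26. Proteasome mRNAs rose relative to the mRNA sum in 32 of 32, with PUP2 at 1.99 and RPT1 at 1.49, but in 12 with TPM as deposited, or 4 with the scaled pseudocount described below, 8 on the 25S rRNA scale and 0 on the spike-in scale (limma, 0 at an unadjusted p under 0.05, and 1 with a block). PUP3 rose by 1.2 here and stood at −0.03 on the spike-in scale. RPN4, which encodes the transcription factor of proteasome genes, went from 12.1 ± 1.75 to 180.1 ± 17.5. Adjusted over the list alone, the counts were the same: 22, 24, 5 higher with 1 lower, 8 higher with 1 lower, and 32. The other 4 lists had 21, 22, 4 and 8 higher with TPM as deposited, 21, 23, 4 and 7 on the 25S rRNA scale, and 7, 4, 1 and 0 on the spike-in scale in limma (11, 10, 1 and 1 in either direction at an unadjusted p under 0.05), where a block of replicate number gave 21, 22, 4 and 5. Median log2 changes of the 5 lists, in the order given, were 4.75, 4.00, 2.43, 2.17 and 1.48. In limma camera their adjusted p values were 7.5e-13, 1.1e-10, 0.0173, 0.000783 and 1.0e-08, against adjusted p = 0.317, 0.317, 0.370, 0.317 and 0.360 with an estimated correlation.

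Mitochondrial and cytoplasmic translation genes went the other way. Of 137 cytoplasmic ribosomal protein mRNAs 136 fell and RPL15B rose (log2 1.79 ± 0.25 SE); reads of near-identical paralogs are split by the quantification, so single members of this family are uncertain. RPS29B went from 86750 ± 7887 to 2024 ± 1559 mRNA TPM and RPL38 from 63450 ± 11220 to 3611 ± 1518 (mean ± SD, n = 3). Ribosome biogenesis mRNAs fell in 45 of 46, with SPB4 not past the threshold; CBF5 and NOP1, both of small nucleolar ribonucleoproteins, were at −5.43 ± 0.35 and −4.60. STM1, whose product binds ribosomes, went from 1460 ± 187 to 34.9 ± 11.3. Initiation factors fell in 23 of 26, among them TIF11 (−3.16) and GCD11 (−2.67), and 1 rose, DED1 (1.03 here, −0.03 with TPM as deposited, −0.01 on the 25S rRNA scale and −0.20 on the spike-in scale). Elongation and termination factors fell in 9 of 14 and none rose. In the list of mitochondrial ribosomal proteins 53 of 69 mRNAs fell and 2 rose, MRP8 and MRP10, and whether MRP8 belongs to that family was not checked. For the poly(A)-binding protein mRNA PAB1 the change was −2.09 ± 0.29 SE. Adjusted over the list alone, the 5 lists had 136, 45, 23, 9 and 55 lower and 1, 0, 1, 0 and 2 higher. With TPM as deposited 136, 45, 25, 13 and 66 were lower, on the 25S rRNA scale 136, 46, 25, 13 and 66, and on the spike-in scale 128, 26, 1, 4 and 0 in limma (134, 43, 10, 7 and 3 in either direction at an unadjusted p under 0.05), or 136, 45, 24, 12 and 65 with a block of replicate number. Their median log2 changes were −6.58, −3.70, −1.73, −1.84 and −1.09, in the same order. Limma camera gave adjusted p values of 4.7e-33, 6.1e-15, 6.0e-06, 0.00536 and 1.1e-06, against adjusted p = 0.317, 0.317, 0.370, 0.396 and 0.321 with an estimated correlation.

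Relative to the mRNA sum, glycolysis and fermentation mRNAs rose in 13 of 17 and fell in 2, the hexokinases HXK1 (−1.97) and HXK2 (−2.77); PGK1 went from 1193 to 6105 mRNA TPM and TDH3 from 2495 to 9507. Cell wall and integrity genes rose in 11 of 19, with HSP150 (3.63) and SED1 (3.26), and fell in 5, with CWP2 (−1.42) and CCW12 (−0.62). Amino acid biosynthesis genes fell in 29 of 36, with ILV5 (−3.57) and HIS1 (−2.76), and 3 rose, LYS1, SER3 and ARG3. Nuclear-encoded respiratory chain genes fell in 21 of 35, with ATP18 (−1.55), and 2 rose, COX5B (2.65) and QCR8 (1.00 here, −0.18 with TPM as deposited, −0.05 on the 25S rRNA scale, −0.24 on the spike-in scale). Genes of the TCA cycle fell in 6 of 11, with LSC2 (−2.76), ergosterol genes in 10 of 18, with ERG2 (−2.38), and cyclins and histones in 6 of 14, and none of these 3 lists had a gene that rose. Among mRNA decay factors 5 rose, with EDC2 at 3.78, 8 fell, with LSM3 at −1.48, and 12 did not pass. Adjusted over the list alone, the decay factors had 5 higher and 7 lower, and the other lists were as above: 13 and 2, 11 and 5, 3 and 29, 2 and 21, 0 and 6, 0 and 10, 0 and 6. Other scales moved these counts: higher and lower were 6 and 4, 8 and 7, 2 and 29, 1 and 31, 0 and 10, 0 and 17, 0 and 13, and for the decay factors 2 and 19 with TPM as deposited. On the 25S rRNA scale they were 7 and 4, 8 and 7, 2 and 30, 1 and 30, 0 and 9, 0 and 17, 0 and 14, and 2 and 19. A block of replicate number on the spike-in scale gave 4 and 3, 7 and 7, 0 and 32, 1 and 32, 0 and 11, 0 and 17, 0 and 12, and 1 and 18, and without the block at most 2 genes of any of these lists passed there. In the order given, with the decay factors last, the median log2 changes were 1.42, 1.28, −1.90, −1.10, −0.98, −0.98, −0.56 and −0.50. Limma camera gave adjusted p = 0.00285, 0.0405, 3.2e-05, 0.000722, 0.0434, 0.00502, 0.0401 and 0.265, against adjusted p = 0.317, 0.452, 0.317, 0.437, 0.539, 0.317, 0.437 and 0.664 with an estimated correlation.

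**Figure D3:**
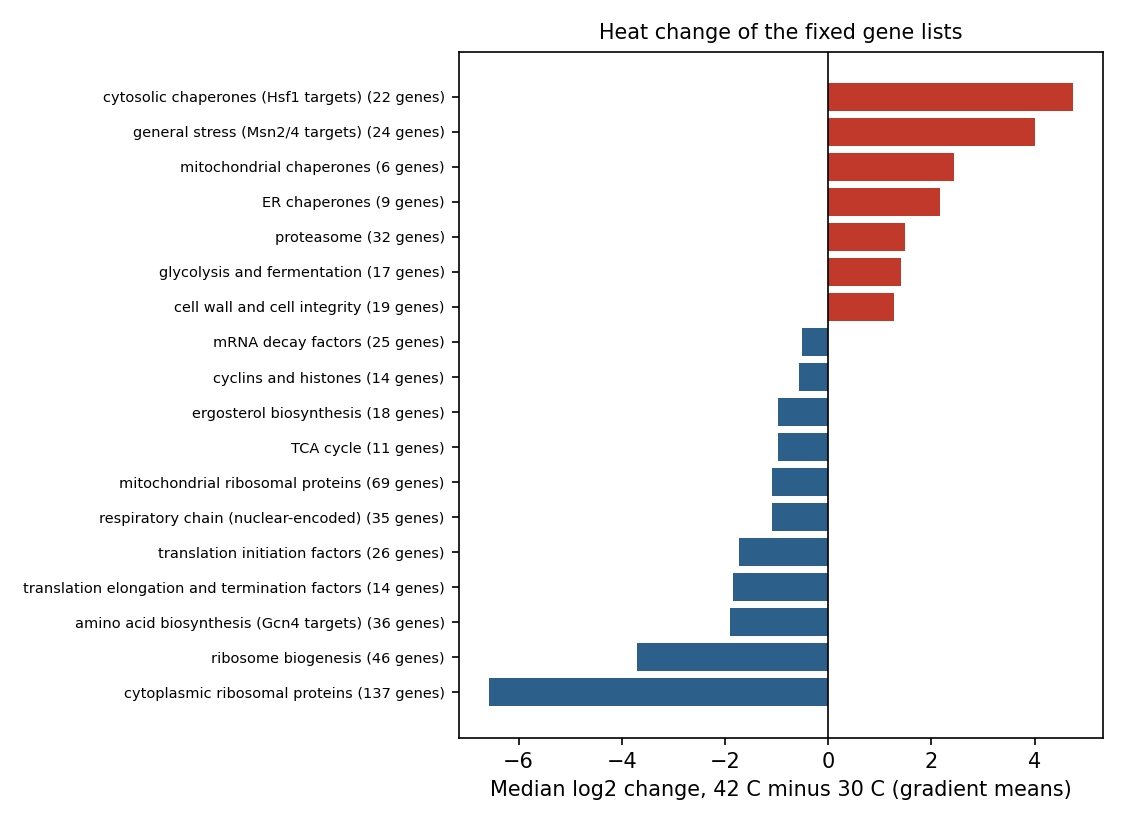
Median log2 change with heat of the 18 tested gene lists, from gradient means, n = 3 per temperature. The sign of each list's median was the same on the mRNA sum, median, quantile, as deposited, spike-in and 25S rRNA scales, but its size was not. As deposited and on the spike-in scale the medians were 0.30 and 0.25 for the proteasome, 0.23 and 0.18 for glycolysis, and 0.098 and 0.042 for the cell wall.

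Of the 18 lists 17 passed limma camera at 5% after Benjamini-Hochberg adjustment, 7 higher and 10 lower, and 0 passed with an estimated correlation, where 17 passed in limma fry. Another split of the same 6 gradients gave 15 lists at the preset correlation. Such a split keeps part of the heat difference, because the temperatures stay unevenly divided between its sides. It gives no count expected without heat, and the number of lists past 5% rests on the correlation used. The 60 other non-coding RNAs, added to the mRNAs in a separate fit of all genes and 19 lists, had 9 higher and 7 lower (2 and 1 adjusted over the list alone) and did not pass as a list in limma camera (adjusted p = 0.500, and adjusted p = 0.782 with an estimated correlation).

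The largest rises over the 4 pools among genes with clear separation were mostly in mRNAs at or near 0 at 30 °C. HSP26, a small heat shock protein, was listed at 0 in 4 of 12 libraries at 30 °C, highest 14.6, and lay between 16710 and 85470 at 42 °C. LSO1 was listed at 0 in all 12 at 30 °C and lay between 539.3 and 3262 at 42 °C, while its paralog LSO2 did not pass (log2 −0.50, limma adjusted p = 0.12). HSP30 (highest 3.68 at 30 °C) reached 1407 to 4424, SPI1 (highest 12.4) 386.5 to 1645 and the aldehyde dehydrogenase ALD3 (highest 11.6) 546 to 1797. CPP3 was listed at 0 in all 12 libraries at 30 °C and in 3 at 42 °C, highest 5640. SSA3, SSA4, BTN2 and RTC3 had no library at 0: SSA4 rose 1672-fold, SSA3 542.9-fold, BTN2 256.4-fold and RTC3 245.8-fold. The largest falls were all in ribosomal protein mRNAs. RPS29A went from 1190 or more to 0 in 10 of 12 libraries, highest 284.7; RPL30 was listed at 0 in 9 of 12 (highest 50.2), RPL31B in 9 (55.7), RPL14A in 8 (25.7), RPL2A in 8 (14.8), RPS21B in 8 (145.0), RPL29 in 7 (393.5), RPL27B in 7 (29.2), RPS22A in 5 (26.2) and RPL26B in 4 (42.1). Among other genes fixed for reporting, HAC1 rose by 1.28, YAP1 by 1.30, GCN4 was at −2.36 ± 0.22 SE, and ACT1 at −0.20 did not pass (limma adjusted p = 0.47).

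Over the 4 pools 2513 of 3949 genes changed with heat in limma at 5%, 1233 higher and 1280 lower. The split depended on the scale. It was 1297 and 1329 with median scaling, 1441 and 1244 with quantile normalization, 659 and 2149 with TPM as deposited, 594 and 2108 on the 25S rRNA scale and 40 and 281 on the spike-in scale (372 and 1968 there with a block of replicate number). The median gene stood at −0.02 on the mRNA sum and at 0.14 with quantile normalization, −0.20 as deposited, −0.94 on the 25S rRNA scale and −1.002 on the spike-in scale. TPM as deposited keeps the pseudocount of 1 on smaller values, and with the pseudocount scaled to the mean mRNA sum, an alternative chosen after the data were seen, it gave 541 and 2185 with the median gene at −1.01. With the replicate number as a block, 2437 genes passed.

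Within single pools, among genes that met the naming rule, HSP26 had the largest rise in each of the 4, to at least 16710 mRNA TPM in every library. SSA4 rose by log2 10.65 ± 0.39 SE in pool 1, 10.61 in pool 2, 10.08 in pool 3 and 10.45 in pool 4, and HSP104 by 7.95, 7.62, 6.94 and 6.44. STM1 was at −4.66, −4.02, −5.90 and −6.21 in the same order, and RPS29B at −6.03 ± 0.86 SE, −5.02, −6.92 and −6.74. In pool 1, RPL29, RPS29A and MIN8 had the largest falls, all listed at 0 in 3 of 3 libraries at 42 °C, from 1844 to 2810 at 30 °C for MIN8. The largest falls elsewhere were those of RPL14A, RPS29A and RPL27B in pool 2, RPL30, RPS8B and RPS26B in pool 3, and RPS28B, RPS21A and RPS29A in pool 4. CPP3 in pools 1 and 2, LSO1 in pools 2 and 3 and HSP30 in pools 3 and 4 were among the 3 largest rises. ACT1 rose by 0.73 in pool 1 and stood at −0.89 in pool 4, both past the threshold, and with median scaling at 0.01 and 0.05, neither past.

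Limma called 2243 genes in pool 1, 2055 in pool 2, 1933 in pool 3 and 2274 in pool 4 at 5%. That fit shares 1 spread per gene over the 8 groups, although the median SD was highest in pool 1 at 42 °C (0.64). Fitted on the libraries of each pool alone, the counts were 1800, 1998, 2084 and 2037. On the mRNA sum the calls of the shared fit were 1569 higher and 674 lower in pool 1, 1311 and 744 in pool 2, 824 and 1109 in pool 3, and 546 and 1728 in pool 4. Median scaling gave 1038 and 1077, 997 and 1053, 1027 and 1006, and 1099 and 1041. With quantile normalization the splits were 1172 and 981, 1123 and 978, 1125 and 971, and 1165 and 947. TPM as deposited gave 68 and 2103, 602 and 1441, 647 and 1731, and 654 and 1885, and with the scaled pseudocount 131 and 2735, 538 and 1392, 531 and 1532, and 537 and 1632. On the 25S rRNA scale they were 317 and 2040, 444 and 1721, 611 and 1513, and 515 and 1767, and on the spike-in scale 23 and 264, 64 and 253, 58 and 393, and 67 and 364. With a block of replicate number the spike-in scale gave 144 and 2024, 388 and 1149, and 264 and 1749 in pools 1 to 3, and 1390 lower of 1782 called in pool 4. The median gene on the mRNA sum moved by 0.65, 0.42, −0.24 and −0.94 in pools 1 to 4. In all 4 pools 497 genes were higher and 547 lower, where independent lists would share 15.03 and 15.6, a value that leaves out that the pools share gradients. 479 and 535 were so with median scaling too. A further 165 genes were higher in one pool and lower in another, and 11 were with median scaling.

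**Figure D4:**
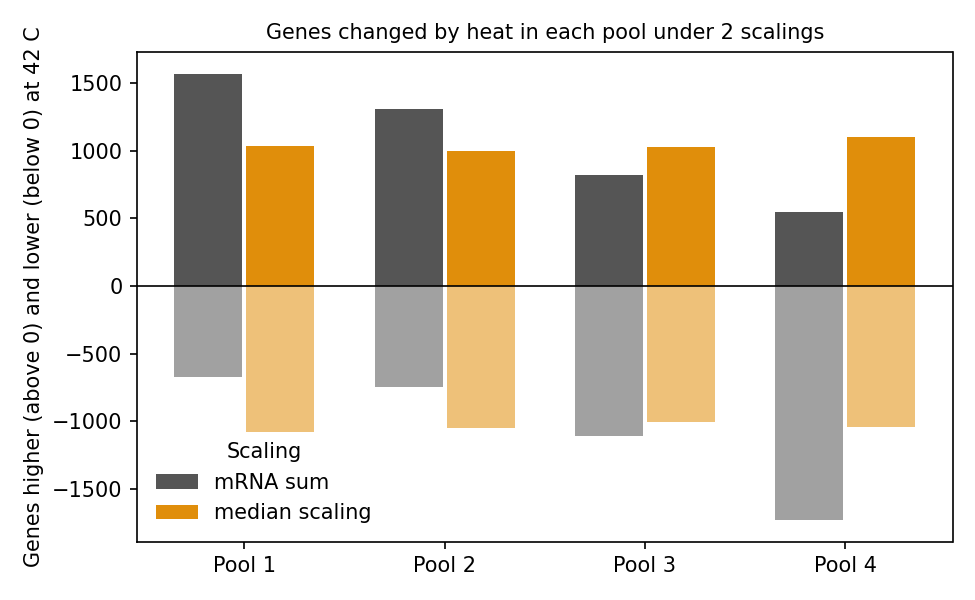
Genes higher and lower at 42 °C in each pool (limma, 5%, 3949 genes, n = 3 per temperature). On the mRNA sum the split turns from mostly higher in pool 1 to mostly lower in pool 4, and with median scaling it is near even in each pool.

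Between pool 1 and pool 4 at 30 °C, IPP1, the cytosolic pyrophosphatase mRNA, went from 84.9 ± 11.4 in pool 1 to 660.4 ± 55.3 in pool 4 (mean ± SD, n = 3; log2 2.95, and 1.83 with median scaling, past the threshold in both). KEG1 (19.5 to 45.2 in pool 4, highest 6.31 in pool 1), PEX11 (29.8 to 78.2, highest 16.7) and SOL4 (12.9 to 34.1, highest 3.94) were the other largest rises, none past with median scaling. HSP82 rose by 2.06, STM1 by 2.29 and ACT1 by 2.30, which were 0.93, 1.16 and 1.17 with median scaling, all past. Of 53 genes higher in pool 1, 50 were so with median scaling too. The 4 largest of these differences were those of OST4, TOM6, CMI7 and WIP1: OST4 of oligosaccharyltransferase lay between 679 and 2113 in pool 1 and at 0 in 3 of 3 in pool 4, TOM6 between 1019 and 1811 against 0 to 291.4, CMI7 between 2139 and 3128 against 0 to 122.2, and WIP1 between 218.3 and 396.2 against 0 to 57.9.

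At 42 °C RUB1, encoding a ubiquitin-like protein, lay between 1386 and 2672 in pool 1 and at 0 in 3 of 3 libraries in pool 4. RPL41B (5058 to 21380 against 0 to 470.8), CPP3 (2245 to 5640 against 0 to 627.9) and TOM5 (2245 to 3384 against 0 to 564.9) were lower in pool 4 as well. Higher in pool 4 were MIN8 (0 in 3 of 3 against 110.3 to 428.1), HBN1 (0 to 44.7 against 50.6 to 111.2), the RNase H2 subunit mRNA RNH203 (0 in 3 of 3 against 14.6 to 34.03) and SHR3 (0 to 22.5 against 24.2 to 50.0), and these 8 calls held with median scaling. With the 42 °C pool 1 libraries left out and pool 2 in their place, MIN8 was at −1.08, the opposite direction. RNH203 was at 1.51, HBN1 at 1.47 and RPL41B at −3.825, and none of these and MIN8 passed in limma. SHR3, RUB1, CPP3 and TOM5 still passed there. GCN4 was at −2.18 ± 0.52 SE, past in both scalings.

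Limma called 1914 genes between pool 4 and pool 1 at 30 °C, 1861 higher and 53 lower, and 332 with median scaling, 186 and 146. At 42 °C it called 518, 67 higher and 451 lower, and 568 with median scaling, 347 and 221; with the gradient as a block, since 4 pools come from each gradient, it called 795. The other scalings gave, higher and lower, 189 and 132 with quantile normalization, 2226 and 99 as deposited (1553 and 68 with the scaled pseudocount), 1252 and 76 on the 25S rRNA scale and 1 and 10 on the spike-in scale at 30 °C. At 42 °C they gave 293 and 197, 2278 and 8 (2866 and 28), 1829 and 69, and 1 and 5. With the gradient as a block the spike-in scale gave 1302 and 87 at 30 °C and 2471 and 38 at 42 °C, where the mRNA sum had 67 and 451. The median gene on the mRNA sum stood at 1.18 at 30 °C and −0.36 at 42 °C. Without 30 °C replicate 2 or replicate 3 the 30 °C count was 1004 or 1135, and without 30 °C replicate 2 or 42 °C replicate 3 the 42 °C count was 328 or 291. Spearman's rho between coding length and the pool 4 to pool 1 change, across genes that are not independent replicates, was 0.249 at 30 °C and 0.062 at 42 °C. At 30 °C the median change was 0.16 for genes under 500 nt and 1.19, 1.35, 1.199 and 1.18 for genes from 500, 1000, 2000 and 3000 nt, so it did not rise further beyond 2000 nt.

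Heat changed the pool 4 to pool 1 difference of RUB1 and BNS1 downward and of MIN8, RNH203 and RPB8 upward, on the mRNA sum and with median scaling. RUB1 lay between 603.8 and 800.3 in pool 1 and between 261.9 and 347.5 in pool 4 at 30 °C, against 1386 to 2672 and 0 in 3 of 3 at 42 °C. BNS1 in pool 4 lay between 37.2 and 66.0 at 30 °C and at 0 in 3 of 3 libraries at 42 °C. MIN8, RNH203 and RPB8, an RNA polymerase subunit, were each listed at 0 in the 3 pool 1 libraries at 42 °C. With those 3 libraries left out, pool 2 took the place of pool 1 at both temperatures. MIN8 was then at −0.44, RPB8 at −0.62 and RNH203 at 3.35, none past in limma. RUB1 and BNS1 passed downward without them, and no size is given because both were listed at 0 in pool 4 at 42 °C. AIM4 upward and CPP3, RPS28A, BIL1, HSK3, RPC10 and RPL7B downward passed on the mRNA sum and not with median scaling, and each has libraries at 0. HSP104 (−1.51), HSP82 (−1.55), STM1 (−1.55), ACT1 (−1.63) and RPN4 (−1.40) fell relative to the mRNA sum and stood at 0.14, 0.11, 0.11, 0.03 and 0.26 with median scaling, none past. With TPM as deposited HSP104 (2.42), HSP82 (2.39) and RPN4 (1.43) passed in limma in the opposite direction, upward, and HSP104 did so on the spike-in scale with a block (1.29). TPM as deposited includes 5S rRNA, which held 25.3% of TPM in pool 1 at 30 °C and 61.4% at 42 °C. On the 25S rRNA scale HSP104, HSP82 and RPN4 were at 0.65, 0.62 and 0.73, none past in limma.

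In limma 1914 genes passed for this change, 12 upward and 1902 downward, with the median gene at −1.56, and with median scaling 12 passed, 6 each way, of which 3 and 6 were calls of the same direction on the mRNA sum. The other splits were 9 and 9 with quantile normalization, 711 and 372 as deposited (872 and 15 with the scaled pseudocount), 14 and 2 on the 25S rRNA scale, and 0 and 1 on the spike-in scale, or 240 and 9 there with the gradient as a block. On simulated data this comparison recovered 0% of genes changed 2-fold and 33.8% of those changed 4-fold, so a low count does not show that few genes changed. Without 30 °C replicate 2 or replicate 3 the count on the mRNA sum was 915 or 1100. Of the lists, proteasome genes passed in 32 of 32 downward (median −1.69) and glycolysis genes in 15 of 17 (median −1.76, 16 adjusted over the list alone, against 32 for the proteasome), with limma camera adjusted p = 1.1e-05 and 2.0e-05, and adjusted p = 0.650 and 0.383 with an estimated correlation. Those medians were −0.03 and −0.10 with median scaling and 1.00 and 1.25 with TPM as deposited. Cytoplasmic ribosomal protein genes tested upward against the other genes (limma camera adjusted p = 1.0e-08, and adjusted p = 0.650 with an estimated correlation). Their median was still −1.01 and their mean −1.12, and 24 of 137 passed downward (14 adjusted over the list alone). Several were near 0 in every pool at 42 °C, such as RPL2A and RPL14A (highest pool mean 8.60 and 9.78 mRNA TPM). That limits how far their difference could fall, and its share in the result was not tested. These 3 of 18 lists became 5 without 30 °C replicate 1, and 1 with median scaling, the respiratory chain, in which 1 of 35 genes passed (limma camera adjusted p = 0.0439, and adjusted p = 0.769 with an estimated correlation). Non-coding RNAs had 17 of 60 downward (10 adjusted over the list alone) and fell further than the median gene, with a median of −2.54 and a mean of −2.93. As a list they still tested upward, because camera weighs moderated t statistics and not folds (limma camera adjusted p = 0.0255, and adjusted p = 0.644 with an estimated correlation).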

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

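Tests of 7 of the 8 explanations below, and the counts over other splits of the samples, were chosen only after the result was seen. For short mRNAs in the mRNA sum the prediction was written before its test, which was not among the comparisons first planned.

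The mRNA to rRNA ratio was lower at 42 °C by a log2 difference of −3.31 in pool 1, and the heat difference of pool 4 exceeded that of pool 1 by 3.43, with the 3 gradients at 42 °C apart from the 3 at 30 °C (2-sided exact permutation p = 0.1, the smallest possible). It was singled out because heat moved 2 pools differently. The 5S rRNA in the denominator is not the whole cause, since over 25S rRNA alone the pool 1 difference was −2.20 (pooled SD 0.10). Nor is the loss of ribosomal protein mRNAs, since the other mRNAs over 25S rRNA were at −0.73 (pooled SD 0.13). Leaving them out still took away most of the pool 1 fall, and in pool 2 the other mRNAs were at −0.12 (pooled SD 0.23). It left most of the heat difference between pool 4 and pool 1. Over 25S rRNA that was 2.17 (pooled SD 0.11) with all mRNAs and 1.58 (pooled SD 0.13) with the other mRNAs. Over the 4 pools the other mRNAs did not fall, at 0.20 (pooled SD 0.14). More rRNA in the pool is argued against by 25S rRNA over spike-in RNA in replicates 2 and 3, at −0.25 (pooled SD 0.31). What stays open is an effect of temperature, or of the filtration and resuspension that went with it, which may act alone or together and was not tested.

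Limma gave 1914 genes whose pool 4 to pool 1 difference changed with heat, 1902 downward, and limma camera gave 3 gene lists at the preset correlation and 0 with an estimated correlation. They were singled out as a difference of one contrast between temperatures. Scaling to the mRNA sum is a candidate explanation for the downward shift, since on the 25S rRNA scale the median gene difference was 0.25 (pooled SD 0.17), with 14 genes upward and 2 downward. Median scaling, with 12 genes, sets the median gene level by construction and decides nothing here. Ribosomal protein mRNAs in that sum are not the whole cause, with the median gene difference at −1.0 (pooled SD 0.13) without them and −1.53 with them, nor are short mRNAs, at −0.90 (pooled SD 0.14), but with both left out it was −0.30 (pooled SD 0.14). On the spike-in scale, which takes the same amount of spike-in per pool as given, the median gene was at 0.68. There 0 genes passed upward and 1 downward, or 240 and 9 with the gradient as a block. With TPM as deposited and the scaled pseudocount the median gene was at 1.17. The downward shift was thus not seen on these scales. An effect of temperature on where mRNAs lie in the gradient stays open for the median gene as a hypothesis, since its direction depends on the scale used.

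Beside the mRNAs, the 5S rRNA share of TPM in pool 1 was 25.3 ± 7.08% at 30 °C and 61.4 ± 17.8% at 42 °C (mean ± SD, n = 3), and 5S over 25S rRNA was higher by a log2 difference of 2.35 in 3 of 3 libraries (exact permutation p = 0.1). In pool 2 it was lower, at −1.06 (pooled SD 0.15), in 3 of 3 libraries (exact permutation p = 0.1). The pool 1 value was singled out as a signal outside the genes compared. Better capture of all short RNA alike is argued against by 5S over 5.8S rRNA, at 1.81 (pooled SD 0.75), since 5.8S rRNA is short too. This does not decide on a capture that differs between short RNAs, and 5.8S over 25S rRNA was itself at 0.54 (pooled SD 0.35). For the 113 other non-coding RNAs listed, carry-over into the pool is argued against by their sum over 25S rRNA, at −0.35 (pooled SD 0.65). That sum cannot decide on small RNAs outside this list, which were not measured. An effect of temperature stays open and was not tested.

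The 10 splits of 3 against 3 samples are too few for a share under 0.05, and in each result the real split was 1 of the 10 splits with a count as large. Every other split divides the real groups unevenly between its sides, so it keeps part of the real difference and adds the rest to the spread. Its count is not that expected without a difference, so these counts decide nothing on chance. The real count and the highest other were 2243 and 4 genes for heat in pool 1, 2055 and 0 in pool 2, 1933 and 0 in pool 3, 2274 and 2 in pool 4, and 2513 and 0 over the pools. They were 1914 and 3 for pool 4 against pool 1 at 30 °C, 518 and 73 at 42 °C, and 1914 and 1 for the heat change of that difference. For the gene lists they were 17 and 15 with heat and 3 and 1 for the change of the difference, at the preset correlation; with an estimated correlation limma camera gave 0 lists for each.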

How the results depend on the processing

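Tests on the 25S rRNA scale, on the spike-in scale with a block, on mRNA over spike-in within replicates 2 and 3, without the 42 °C pool 1 libraries, with pool 3 in place of pool 4, on genes of at least 600 nt, with median scaling of the lists, with a scaled pseudocount, and for pool 4 with a block or alone were chosen only after the result was seen.

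A filter of 50 mRNA TPM left 1228, 1151, 1183 and 1268 genes changed by heat in pools 1 to 4, 1363 over the pools, 1050 and 343 between pool 4 and pool 1 at 30 °C and 42 °C, and 975 for the heat change of that difference. Quantile normalization gave 321 at 30 °C and 18 for that change, and median scaling 332 and 12, with 1 list. TPM as deposited gave 2286 at 42 °C and 1083 for the change, with 14 lists. The 25S rRNA scale gave 1898 and 16. On the spike-in scale the heat counts were 287, 317, 451 and 431 in pools 1 to 4 and 321 over them, and those of the pool contrasts 11, 6 and 1; with the gradient as a block on that scale the last 2 became 2509 (2471 higher, 38 lower) and 249 (240 upward, 9 downward), against 67 and 451, and 12 and 1902, on the mRNA sum. A block of gradients took the 42 °C pool count from 518 to 795. Genes of at least 600 nt gave 282 there, fits without the 42 °C pool 1 libraries 317, and pool 3 against pool 1 at 30 °C gave 66. With an estimated correlation 0 lists passed in limma camera for heat and 0 for the change of the pool difference, where limma fry called 17 and 17 and 17 and 3 passed with the preset correlation.

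Leaving out 1 replicate of a temperature gave 1848 to 2249, 1673 to 1998, 1541 to 1879 and 1903 to 2229 genes in pools 1 to 4, 2120 to 2474 over the pools, 1004 to 2107 and 291 to 468 between pool 4 and pool 1 at 30 °C and 42 °C, 915 to 1872 for the change, and 15 to 17 and 3 to 5 lists. The ratio ran from −3.67 to −2.92 in pool 1, −1.32 to −0.99 in pool 2, −0.61 to −0.44 in pool 3, 0.08 to 0.15 in pool 4, −1.32 to −1.08 over the pools and 3.005 to 3.82 for pool 4 minus pool 1.

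Over 25S rRNA the ratio differences were −2.20, −1.51 and −0.027 in pools 1, 2 and 4 and 2.17 for pool 4 minus pool 1; over 18S rRNA −2.10, −1.42 and 0.041, with −0.98 over the pools and 2.15. Without the 20 most abundant mRNAs pools 1, 3 and 4 were at −2.73, −0.78 and −0.39, and pool 4 minus pool 1 at 2.33. Over spike-in RNA within replicates 2 and 3 pools 1, 2 and 4 were at −2.49, −0.85 and 0.058, the pools together at −0.95 and the difference at 2.55.

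Heat over the pools turned sign with TPM as deposited for DED1 (−0.033), TEF2 (−0.69), QCR8 (−0.18), IDH2 (−0.78), HHF1 (−1.002), HHT2 (−0.98) and HTA1 (−1.07), on the 25S rRNA scale for DED1 (−0.012), TEF2 (−0.80), QCR8 (−0.048), HHF1 (−0.92), HHT2 (−0.88) and HTA1 (−1.03), and on the spike-in scale for PUP3 (−0.032), DED1 (−0.20) and QCR8 (−0.24). With a block on the spike-in scale it did for PUP3 (−0.032), DED1 (−0.20), TEF2 (−0.98), QCR8 (−0.24), IDH2 (−1.18), HHF1 (−1.11) and HTA1 (−1.22). Of these, DED1, QCR8 and PUP3 did not pass in limma where they turned, and the others passed downward.

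The heat change of the pool difference turned sign with TPM as deposited for RPS28A (0.13), RPC10 (0.58), SSA4 (3.88), HSP104 (2.42), HSP82 (2.39), LSO2 (1.67), HAC1 (0.99), GCN4 (0.66), ACT1 (0.53), RPN4 (1.43) and YAP1 (0.36), all past 5% in limma but RPS28A, RPC10, ACT1 and YAP1, and with median scaling for HSP104 (0.14), HSP82 (0.11), STM1 (0.11), ACT1 (0.034) and RPN4 (0.26). On the spike-in scale it did for HSP104 (1.29), HSP82 (1.26), STM1 (0.64), ACT1 (1.04), RPN4 (1.34) and YAP1 (0.83), and with a block added also for HSP12 (1.68), SSA4 (2.77) and HAC1 (1.86), the first 6 keeping their values, and HSP12, SSA4, HAC1 and HSP104 passed upward there. Quantile normalization turned ACT1 (0.074) and RPN4 (0.090), and the 25S rRNA scale HSP104 (0.65), HSP82 (0.62), STM1 (0.44), ACT1 (0.52), RPN4 (0.73) and YAP1 (0.31). None of these passed in limma where they turned. Without the 42 °C pool 1 libraries MIN8 was at −0.44 and RPB8 at −0.62, and MIN8 at −1.08 for the pools at 42 °C. Among the lists, limma fry, which tests against no change, put ribosomal proteins (−1.12, not past 5%), ribosome biogenesis (−1.77) and the respiratory chain (−1.13) downward by the list's mean. TPM as deposited turned Hsf1 chaperones (2.12), mitochondrial (1.24) and ER chaperones (0.72), general stress (1.67), the proteasome (0.74), ribosomal proteins (−0.35), ribosome biogenesis (−0.73), glycolysis (0.94) and the cell wall (0.57), each as the list's mean against other genes and each past 5% in limma camera.

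Counting every alternative of every result, values for named genes were as before in 3223 cases, gained a call in 56, lost it in 233 and turned sign in 65. For gene lists these numbers were 365, 22, 33 and 12, and summary values held in 208 cases, moved in 58 and turned sign in 2. For heat in pool 4 a fixed block of gradients, and contrasts of several pools, were planned and not run. A gradient has 1 temperature, and the contrasts need more than 1 pool. Run in their place, unplanned, were a random block of gradients (2266 genes) and a block of replicate number (2222 genes).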

Other observations

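No tests were made in this part, and its values were picked out only after the result was seen.

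Spike-in RNA placed the mRNA of a gradient differently at the 2 temperatures: pools 1 to 4 held 20.98, 30.4, 32.2 and 16.4% of it at 30 °C and 6.33, 28.0, 31.1 and 34.6% at 42 °C. For 25S rRNA the shares were 24.3, 22.6, 29.0 and 24.1% at 30 °C and 18.7, 32.4, 20.9 and 28.1% at 42 °C. These shares take the same amount of spike-in per pool as given.

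LSO1 and CPP3 were listed at 0 in all 12 libraries at 30 °C, and 673 to 882 mRNAs were listed at 0 in each library at that temperature, so a value of 0 here does not show that an mRNA is absent. RPL15B rose with heat while RPL15A was at −6.43, and the split of reads between such paralogs was not checked.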
